A study of Vitis vinifera with 8 samples.

How the data were processed

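Messenger RNA from deseeded berries of L1 Pinot Meunier microvines was sequenced by the authors in 8 single-end Illumina libraries, 2 biological replicates for each combination of stage and temperature. The authors' processing notes name Bowtie 0.12.7 and TopHat 1.2.0 for read alignment. The genome build, the gene annotation, the counting tool, the strand setting and the handling of reads with several matches are not given in the sources used here. The values are RPKM as deposited, made by the authors by dividing the reads of each gene by its length in kilobases and by the reads of the library (in units of 1e+06), with 1 column per library and no pooling of replicates. The microarray comparison named in the title is not analysed here.

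Each file listed 25771 numeric gene IDs, and 18647 of them matched a gene in the reference table. Of the matched genes 309 carry a symbol other than a placeholder, and 250 of these entered the tests. Genes without such a symbol were counted in every total and left unnamed, apart from a few given by their placeholder.

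Whole read numbers were recovered from the steps of the RPKM values. In the order pre-véraison at 16 °C, pre-véraison at 38 °C, post-véraison at 16 °C and post-véraison at 38 °C, with replicate 1 before replicate 2, the library denominators were 6047199, 7046244, 7810965, 8821163, 8167704, 11243341, 9459339 and 10121400 reads. Of 20845 genes above 0 in at least 3 libraries, 20773 (99.7%) gave whole reads and a whole length; 1708 genes above 0 in only 1 or 2 libraries were not recovered, and 3218 were listed at 0 in all libraries. For a gene of the median recovered length of 1541 bp, 3 reads made 0.17 to 0.32 RPKM, depending on the library. On reads simulated from 20773 genes, 20344 of the 20464 above 0 in at least 3 libraries were recovered. All of these (100%) were as simulated up to a divisor common to all reads of the gene. Recovered reads and lengths may therefore be too small by such a divisor. Replicates had a Pearson r of 0.993 to 0.995, and their reads differed by more than sampling noise (mean chi-square per gene 4.05 to 13.4, where 1 is sampling noise), so no library was a copy of its replicate.

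Genes with at least 1 RPKM in at least 2 of the 8 libraries were tested, 16777 in all. Values were transformed as log2(RPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (a mean for each of the 4 groups, empirical Bayes with an intensity trend, two-sided tests, 4 residual and 6.06 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and an adjusted p under 0.05 counted as a call. The 5 comparisons were heat before véraison, heat after véraison, the interaction of stage and temperature, and the stage difference at 16 °C and at 38 °C. Standard errors are the moderated ones of the fit, SDs are of RPKM over n = 2 libraries. The relation of the heat responses was measured by Pearson and Spearman correlation and by overlaps against the product of the list sizes divided by the genes tested. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

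Comparisons, tests, alternatives, gene lists and the rule for naming genes were set before the data were examined. For the 2 heat comparisons and the stage difference at 16 °C the rule named the 8 genes with the largest rise and the 8 with the largest fall, and for the other 2 comparisons the 4 each way. Eligible genes had passed the threshold, had no overlap between the libraries of the higher and the lower group, and had a mean of at least 5 RPKM in the higher group; for the interaction the part on overlap was not used. Up to 3 members of each list with the smallest adjusted p were also named. Genes without a descriptive name were passed over: 346 among the rises and 292 among the falls with heat before véraison, 19 rises after véraison, 135 and 148 in the interaction, 50 and 190 in the stage difference at 16 °C and 24 and 162 at 38 °C.

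Gene lists were word patterns, and gene names here are mostly short symbols, so 23 of the 30 lists matched no gene. Of the 7 that matched, 1 had at least 3 tested members (aquaporins). Checks that needed the lists of seed, clock and reference genes were not made for that reason. The families of gene symbols in the report were drawn up after the names and values had been seen. Lists were tested with camera in limma at a preset correlation of 0.01 and with the correlation estimated from residuals, with Benjamini-Hochberg over the lists of each comparison, families and fixed lists apart. Aquaporins were the only fixed list tested in this way, so their camera adjusted p equals the unadjusted p.

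Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 RPKM, median-ratio scaling, quantile normalization, rescaling to a common total, limma without trend, a robust prior, only the 4 libraries compared, the replicate number as a block, an adjusted p under 0.01, a fold change of at least 2, and each library left out in turn. The replicate numbers were not treated as pairs: across groups, the differences between replicates had correlations of -0.05 to 0.03. The other planned tests for read counts were not run, since the deposited unit is RPKM; limma voom on the recovered reads was added after the data had been seen, with 16730 genes.

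The fit was tested on simulated reads, with 200 changed genes among 16517 and log2 changes after véraison of 0.5 times those before. The simulation used the same dispersion (spread between replicates beyond counting noise) of 0.00913 throughout. The measured spread was uneven: chi-square per gene between the unheated pre-véraison replicates had a mean of 13.4 and a median of 1.10. The rates below therefore hold for the simulated spread, and recovery of genes with a larger spread was not tested. Of the genes changed before véraison by 1.5-, 2-, 4- and 8-fold, heat before véraison recovered 16, 88, 100 and 100%. Heat after véraison recovered 0, 2, 88 and 92%, and the interaction 0, 6, 34 and 72%. Heat before véraison called 18 unchanged genes beside 8, 44, 50 and 50 changed ones. Heat after véraison called 6 beside 0, 1, 44 and 46, and the interaction 4 beside 0, 3, 17 and 36. In each comparison the share of unchanged genes among the calls was above the threshold of 0.05, most so for heat before véraison. That share was not tested for the calls in the measured libraries.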

Results

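The data are RPKM values (reads scaled by gene length and by the reads of the library) from single-end Illumina mRNA sequencing of deseeded grape berries. The plants were microvines, a dwarf grapevine derived from the L1 layer of Pinot Meunier, kept in a growth room at 16 °C. Berries were taken before véraison (5 to 6 weeks after flowering) and after it (12 to 14 weeks); véraison is the onset of ripening, when berries soften, colour and gain sugar. At each stage, berries were sampled at 16 °C at 9 AM, and again at 10 AM, 1 hour after the room was set to 38 °C. The series design text states 2 biological replicates for each of the 4 combinations of stage and temperature, which makes 8 libraries. Each file listed 25771 genes with 1 RPKM value per library. The 10 most abundant genes took 7.82 to 11.7% of the reads of the pre-véraison libraries and 24.0 to 26.7% of those of the post-véraison libraries. Since 16 °C always went with 9 AM and 38 °C with 10 AM, every heat comparison below also holds the hour between samplings.

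The first question was which transcripts changed after 1 hour at 38 °C in berries before véraison. HSP101, a chaperone that dissolves aggregated proteins, rose from 6.73 ± 0.55 RPKM at 16 °C to 1010 ± 92.2 RPKM at 38 °C (SD, n = 2), a ratio of means of 150. HsfA2, a heat stress transcription factor, rose from 2.41 ± 1.02 to 610 ± 67.9 RPKM (SD, n = 2). The endoplasmic reticulum chaperone BiP rose from 2.96 ± 0.42 to 9.77 ± 0.03 RPKM (SD, n = 2). On the scale of log2(RPKM + 1), the rise was 7.03 ± 0.17 (SE) for HSP101, 7.51 ± 0.27 for HsfA2 and 1.45 ± 0.15 for BiP, with limma adjusted p-values of 2.9e-09, 3.1e-08 and 9.5e-05.

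Other named genes rose by less than HSP101 and HsfA2 and by more than BiP. The class IV chitinase gene CHI4C rose by 3.11 ± 0.31 (SE) log2 units, the dehydroascorbate reductase gene DHAR by 2.48 ± 0.15, the calcium-regulated kinase gene CIPK02 by 1.93 ± 0.21 and the lipoxygenase gene LOXO by 1.93 ± 0.31. A gene listed under the symbol WKRY rose by 1.64 ± 0.19. Among the genes that fell, MYBC2-L1, a MYB repressor of flavonoid synthesis, went from 74.8 ± 13.1 to 17.2 ± 3.47 RPKM (SD, n = 2), a change of -2.06 ± 0.20 (SE) log2 units. The transcription factor gene bZIPC22 changed by -1.78 ± 0.18 log2 units, MYBCS1 by -1.51 ± 0.13, MYB30 by -1.24 ± 0.17, CTR2 by -1.50 ± 0.23 and CIPK19 by -1.13 ± 0.16. The chalcone synthase genes CHS2 and CHS1, which encode the entry enzyme of flavonoid synthesis, changed by -1.58 ± 0.24 and -1.07 ± 0.17. The limma adjusted p of all these genes lay between 1.2e-06 (DHAR) and 0.0016 (CHS1).

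**Figure D1:**
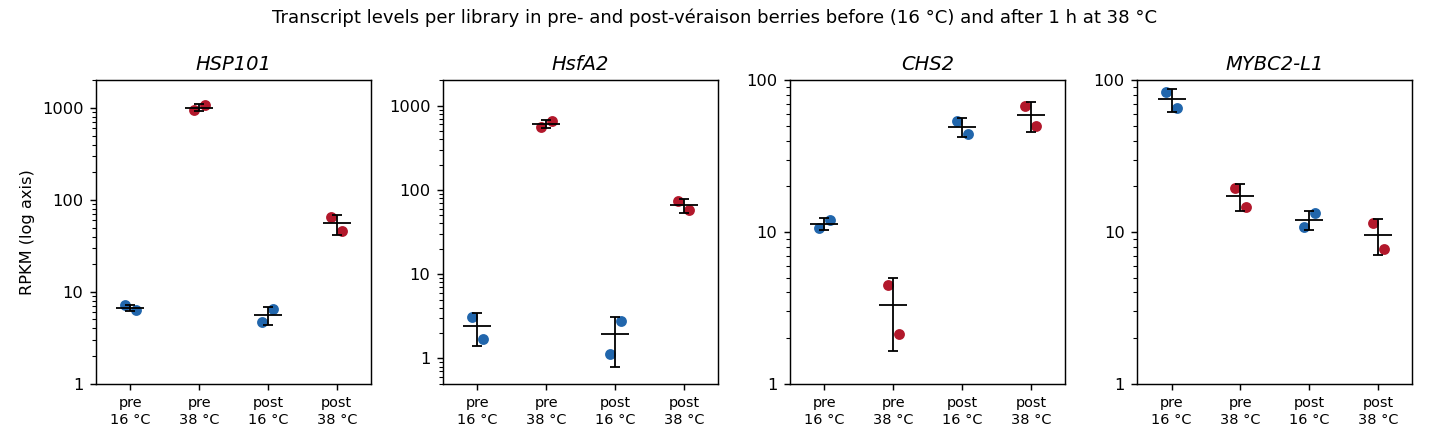
RPKM (log axis) of HSP101, HsfA2, CHS2 and MYBC2-L1 in each of the 8 libraries, with pre and post standing for berries before and after véraison; points are libraries, horizontal bars are group means and error bars are SD (n = 2). HSP101 averaged 1010 RPKM in heated pre-véraison berries and 55.4 RPKM in heated post-véraison berries, against 6.73 and 5.60 RPKM at 16 °C.

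Aquaporins were the 1 gene list fixed beforehand that had at least 3 tested members. Of its 10 tested members, 2 rose and 2 fell before véraison, and the count adjusted over the list alone was also 2 and 2. The rises of PIP2;2 and TIP2;1 were 0.46 ± 0.11 and 0.47 ± 0.15 (SE) log2 units. With no filter on low values, rescaling to a common total, limma without trend or a replicate block over all libraries, 3 aquaporins were called. PIP2;2, PIP2 and PIP1;1 stayed called there, so the call of TIP2;1 was lost. PIP2;2 rose from 500 ± 35.6 to 691 ± 68.9 RPKM (SD, n = 2), while PIP2 fell from 196 ± 24.2 to 118 ± 12.3 RPKM and PIP1;1 from 26.3 ± 0.53 to 12.2 ± 1.10 RPKM. The rise of PIP2;2 was not called with quantile normalization (limma adjusted p = 0.097), with only the 4 libraries compared (0.080) or without replicate 1 of the unheated or of the heated berries (0.067 and 0.085, where 0 aquaporins rose and 2 fell), and the fall of PIP1;1 not with a pseudocount of 0.1 (0.067). The list as a whole did not pass the set test (camera adjusted p = 0.12, and adjusted p = 0.19 with an estimated correlation). Other fixed lists held only 1 or 2 tested genes: HSP101 and HsfA2 are given above, WRKY20 fell by 0.48 ± 0.12 (SE) log2 units (limma adjusted p = 0.019; 0.054 with only the 4 libraries compared, and 0.060 to 0.12 without replicate 1 of the unheated or either replicate of the heated berries), and WRKY2, the sugar transporter gene SWEET15 and the chitinase gene chit1a were not past the threshold, with log2 differences of -0.12, -0.30 and 0.05.

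Further families were drawn up from gene symbols after the values had been seen, so their counts are descriptions and not independent evidence. Of 14 flavonoid pathway enzymes, 3 fell and 0 rose (CHS1, CHS2 and the flavonol synthase gene FLS1, at -1.31 ± 0.24 log2 units); at an unadjusted limma p under 0.05, 4 were lower and 1 higher, and limma voom called 3 lower and 0 higher. Of 9 regulators of that pathway, 4 fell and 0 rose (MYBC2-L1, MYBCS1, MYC1 and MYB12), against 4 lower and 2 higher at an unadjusted limma p under 0.05 and 4 lower and 0 higher by limma voom. With median-ratio scaling 3 of the regulators fell, and without replicate 1 or replicate 2 of the heated berries 2 fell. Of 25 calcium sensor and sensor-kinase genes (CBL and CIPK), 4 rose and 7 fell in limma over all genes, 4 and 11 adjusted over the list alone, 4 and 11 at an unadjusted p under 0.05, 4 and 11 by limma voom, and 4 and 5 with median-ratio scaling. Without replicate 1 of the unheated berries 3 rose and 4 fell, and without replicate 2 of the heated berries 2 rose and 3 fell. Among the calls were CIPK01 at 0.93 ± 0.12 and CIPK15 at -0.88 ± 0.09 log2 units. Of 5 chloroplast and chlorophyll genes, 3 fell (2 with median-ratio scaling), among them the magnesium chelatase gene CHLH, from 141 ± 5.91 to 70.9 ± 8.13 RPKM (SD, n = 2). None of the 3, CHLH, NDHM and PSBP2, was called without replicate 1 of the unheated berries (limma adjusted p = 0.053, 0.084 and 0.16) or of the heated berries (0.083, 0.061 and 0.14), and without replicate 2 of the heated berries NDHM and PSBP2 were not (0.057 and 0.092). The fall of MYC1 was not called without replicate 1 or 2 of the heated berries (0.059 and 0.065). With the preset correlation the 3 heat shock genes passed camera before véraison (adjusted p = 6.0e-07), and the other families did not (camera adjusted p = 0.21 to 0.80). With an estimated correlation none of the families passed camera (adjusted p = 0.19 for the 3 heat shock genes, and 0.64 to 0.86 for the others).

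Of 16777 genes tested with limma, 1335 were higher and 2082 lower at 38 °C before véraison at an adjusted p under 0.05; 628 and 461 of them changed at least 2-fold. With median-ratio scaling the split was 1488 higher and 1515 lower. Only 67 of the 3417 called genes carry a descriptive name. Without replicate 2 of the heated pre-véraison berries the count was 2013.

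The same question was asked of berries after véraison. HSP101 rose from 5.60 ± 1.21 to 55.4 ± 13.8 RPKM (SD, n = 2), a ratio of means of 9.91, and HsfA2 from 1.93 ± 1.15 to 65.4 ± 11.8 RPKM. The log2 changes were 3.09 ± 0.17 and 4.55 ± 0.27 (SE), with limma adjusted p-values of 1.4e-05 and 1.5e-05. No other named gene passed the threshold in limma. At an unadjusted p under 0.05, 20 named genes were higher and 10 lower, and limma voom on recovered reads called 4 higher and 1 lower. CHI4C was at 1.04 ± 0.31 log2 units (limma adjusted p = 0.22), CIPK02 at 0.88 ± 0.21 (limma adjusted p = 0.11), LOXO at 0.77 ± 0.31 (limma adjusted p = 0.43) and DHAR at 0.42 ± 0.15 (limma adjusted p = 0.33). CHI4C and CIPK02 were called without replicate 1 of the unheated berries (limma adjusted p = 0.027 and 0.025) and by limma voom (adjusted p = 0.0079 and 0.0027). BiP was at 4.01 ± 0.17 RPKM before and 4.12 ± 0.23 RPKM after heating (SD, n = 2).

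None of the 10 aquaporins was called after véraison in limma, over all genes or adjusted over the list alone; at an unadjusted p under 0.05, 0 were higher and 1 lower, and limma voom called 0. The members with the smallest p were TIP1;2, TIP1;1 and PIP2;2, at -0.44, -0.32 and -0.18 log2 units. The list did not pass the set test (camera adjusted p = 0.061, and adjusted p = 0.13 with an estimated correlation). Of the 14 flavonoid enzymes 0 were called in limma, with 2 higher and 1 lower at an unadjusted p under 0.05 and 0 by limma voom. CHS2 was at 49.1 ± 7.05 RPKM at 16 °C and 59.0 ± 13.2 RPKM at 38 °C (SD, n = 2).

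Over all genes, limma called 183 higher and 27 lower at 38 °C after véraison, and 117 and 6 of these changed at least 2-fold. The total of 210 was 36 when only the 4 post-véraison libraries entered the fit, and 104 or 107 without replicate 1 or 2 of the heated berries. Summed over 38 genes induced by heat before véraison, replicate 2 of the unheated post-véraison berries held 233 RPKM and replicate 1 held 179 RPKM; without replicate 2 the count was 148.

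The next comparison asked whether the heat response differed between the stages, tested as the interaction of stage and temperature. The rise of HSP101 was 3.94 ± 0.25 (SE) log2 units smaller after véraison than before (interaction -3.94, limma adjusted p = 1.2e-05), and the interaction was -2.96 ± 0.38 for HsfA2 (limma adjusted p = 0.0010). DHAR had an interaction of -2.06 ± 0.21 (limma adjusted p = 2.2e-04) and CHI4C of -2.07 ± 0.43 (limma adjusted p = 0.017). In the other direction, the fall seen before véraison was smaller or absent after it for CHS2, with an interaction of 1.83 ± 0.34, for MYBC2-L1 (1.75 ± 0.28), for bZIPC22 (1.39 ± 0.25) and for PIP1;1 (1.29 ± 0.24), with limma adjusted p-values of 0.0095, 0.0044, 0.0078 and 0.010. PIP1;1 was already at 0.13 ± 0.03 RPKM in unheated post-véraison berries (SD, n = 2), which left little room for a fall.

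Among aquaporins, 1 of 10 had a positive and 1 a negative interaction over all genes (PIP1;1 and PIP2;2), and 2 and 2 when adjusted over the list alone. The list passed the set test in the negative direction with the preset correlation (camera adjusted p = 0.026) and not otherwise (adjusted p = 0.087 with an estimated correlation). Its median interaction was -0.39 and its mean -0.16 log2 units. In total 662 genes had a positive and 592 a negative interaction; with median-ratio scaling these were 416 and 624. CHS1 and FLS1 also had positive interactions (0.98 ± 0.25 and 1.35 ± 0.34, limma adjusted p = 0.040 and 0.039), which were not called with median-ratio scaling (0.077 and 0.059). Of the 14 flavonoid enzymes 3 had a called interaction, and 1 did without replicate 1 of the unheated pre-véraison berries, replicate 2 of the unheated post-véraison berries or any 1 of the 4 heated libraries. That of PIP2;2 was not called with quantile normalization (0.099), and no aquaporin had a called negative interaction without replicate 1 of the unheated or of the heated pre-véraison berries or either replicate of the heated post-véraison berries. The total of 1254 was 711 without replicate 2 of the heated pre-véraison berries, and 696 or 748 without replicate 1 or 2 of the heated post-véraison berries. The CHI4C interaction was not called with a pseudocount of 5 (limma adjusted p = 0.25), with no filter on low values (0.065), or without replicate 2 of the unheated pre-véraison berries (0.052), replicate 1 or 2 of the heated pre-véraison berries (0.087 and 0.073) or replicate 1 of the heated post-véraison berries (0.074). Over its 22 alternatives the adjusted p ran from 0.0020 to 0.25. That of PIP1;1 was not called with a pseudocount of 0.1 (limma adjusted p = 0.059) or with limma voom (adjusted p = 0.13), with a range of 0.0015 to 0.13.

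The responses of the 2 stages were then set side by side across genes. Of the 1335 genes that rose before véraison, 158 also rose after it, where 14.6 would be shared by independent lists of these sizes, and of the 2082 that fell, 18 also fell, against 3.35. No gene was called in opposite directions. Of the 158 genes that rose at both stages, 142 had the larger rise before véraison, and for 116 of them that difference was called in the interaction; their median rise was 3.17 log2 units before and 1.29 after véraison. HSP101 and HsfA2 were among these genes. Over all 1335 risers, 1077 (80.7%) had a positive difference after véraison, 576 had a smaller response by the interaction and 4 a larger one. Over the 2082 fallers, 1342 (64.5%) had a negative difference after véraison, 616 had a smaller response by the interaction and 0 a larger one. Risers and fallers were chosen by the same pre-véraison libraries that enter the interaction, which by itself favours smaller responses after véraison. The ratios over separate pairs of pre-véraison libraries, given further on, avoid this. With median-ratio scaling, 416 of all tested genes had a positive interaction, fewer than the 616. The 2 log2 fold changes had a Pearson r of 0.56 and a Spearman rho of 0.29 across the 16777 genes, which are not independent replicates. The 2 comparisons share no library, but the fit gives both the same standard error for a gene. Genes with a small standard error are more easily called in both, so 14.6 and 3.35 may be too low as references.

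**Figure D2:**
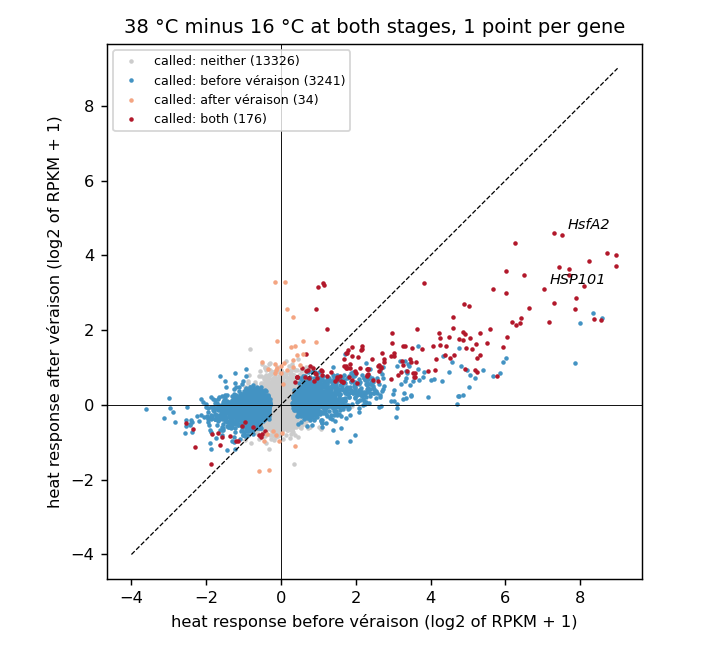
Change from 16 to 38 °C of each tested gene before véraison (horizontal axis) and after it (vertical axis), both as differences of log2(RPKM + 1); colours give the stage at which limma called the gene and the dashed line marks equal change. Most of the genes that rose at both stages lie below the dashed line (142 of 158), and HSP101 and HsfA2 are labelled.

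A further comparison asked how berries before and after véraison differed at 16 °C. The thaumatin-like protein gene TL3 was at 161 ± 37.9 RPKM before véraison and 13033 ± 194 RPKM after it (SD, n = 2), a ratio of means of 80.9, and the ripening-induced gene MRIP1 was at 208 ± 17.9 and 15792 ± 106 RPKM. GRIP22, another ripening-induced gene, was at 0.62 ± 0.07 and 489 ± 26.7 RPKM. In the anthocyanin branch, GST4 was at 0.29 ± 0.40 and 329 ± 4.87 RPKM (SD, n = 2). It is a glutathione S-transferase gene linked to vacuolar transport of anthocyanins. UFGT, which glucosylates anthocyanidins, was at 0.05 ± 0.07 and 40.6 ± 2.02 RPKM. The chalcone synthase gene CHS3, of the entry step of flavonoid synthesis, was at 2.24 ± 0.43 and 302 ± 24.8 RPKM (SD, n = 2). The germin-like gene GER7 was listed at 0 in both unheated pre-véraison libraries and at 192 ± 82.7 RPKM after véraison, at least 759-fold higher against a floor of 3 reads over the group. The stilbene synthase gene VINST1 was at 0.82 ± 0.51 and 78.5 ± 14.4 RPKM. Over the alternatives the log2 difference ran from 5.98 to 10.5 for GST4 and from 5.23 to 11.1 for GER7, so these sizes depend on the processing.

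Genes lower after véraison included PPO (polyphenol oxidase), from 186 ± 19.0 to 1.66 ± 1.66 RPKM, the photosystem gene PSBP1, from 608 ± 20.1 to 26.6 ± 1.22 RPKM, and CHLH, from 141 ± 5.91 to 6.58 ± 1.71 RPKM (SD, n = 2). OMT1, VPRP1 and the peroxidase gene POD1 had log2 differences of -4.53 ± 0.18, -4.02 ± 0.28 and -3.92 ± 0.23 (SE). Over the alternatives OMT1 ran from -8.20 to -2.52 and POD1 from -4.30 to -2.97. The largest limma adjusted p among the genes of this and the preceding paragraph was 6.2e-07 (VPRP1).

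Of the 10 aquaporins, 8 were lower and 0 higher after véraison, in limma over all genes and adjusted over the list alone; at an unadjusted p under 0.05 the counts were also 8 and 0, and limma voom called 8 lower and 0 higher. PIP1;1 and TIP4 differed by -4.60 ± 0.17 and -3.58 ± 0.18 (SE) log2 units, and PIP2 was at 196 ± 24.2 RPKM before and 11.3 ± 1.16 RPKM after véraison (SD, n = 2). Over the alternatives the log2 difference ran from -7.26 to -2.61 for PIP1;1 and from -7.19 to -1.70 for TIP4, so these sizes depend on the processing. The list passed the set test with both correlations (camera adjusted p = 0.0041, and adjusted p = 0.044 with an estimated correlation). These equal the unadjusted p, since no other fixed list was tested, while the families below were adjusted over all families. With median-ratio scaling 8 members were lower and 1 higher.

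Among the families drawn up afterwards, 10 of 14 flavonoid enzymes were higher and 4 lower (with median-ratio scaling 10 and 2). The members that were lower were LDOX, FLS1, and the proanthocyanidin genes LAR2 and ANR, at -0.80, -1.59, -2.88 and -1.06 log2 units. Of 14 pathogenesis-related proteins, 10 were higher and 2 lower (PR10.5 and PR10.7), and of 5 phenylpropanoid and stilbene genes, 4 were higher and 0 lower. Of 10 ripening-induced proteins 6 were higher and 2 lower. With the preset correlation these 4 families passed camera (adjusted p = 6.0e-06, 2.4e-06, 2.2e-05 and 3.1e-05), and with an estimated correlation none did (adjusted p = 0.17, 0.081, 0.29 and 0.16). All 5 chloroplast and chlorophyll genes were lower (camera adjusted p = 0.020, and adjusted p = 0.70 with an estimated correlation). Of 14 sugar transport and invertase genes, 3 were higher and 7 lower, and 6 and 6 with median-ratio scaling; SWEET15 rose from 84.0 ± 4.40 to 1530 ± 213 RPKM and the hexose transporter gene HT5 from 0.49 ± 0.05 to 27.9 ± 7.47 RPKM (SD, n = 2).

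**Figure D3:**
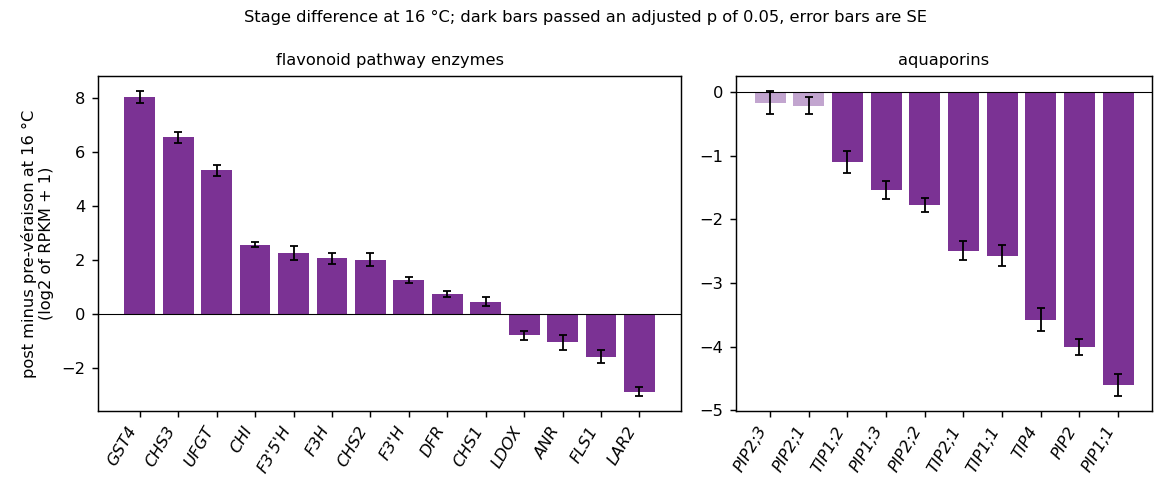
Difference between post- and pre-véraison berries at 16 °C, in log2(RPKM + 1), for the 14 tested flavonoid enzymes and the 10 tested aquaporins; bars are estimates from 2 libraries per group, error bars are SE, and dark bars passed a limma adjusted p of 0.05. GST4 (8.04), CHS3 (6.55) and UFGT (5.31) stand highest among the enzymes on this scale, and PIP1;1 (-4.60) lowest among the aquaporins. With limma voom UFGT (8.80) stood above CHS3 (7.03).

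Limma called 2498 genes higher and 9557 lower after véraison at 16 °C, 79.3% of them lower. With median-ratio scaling, which moved the median of all genes by 0.52 log2 units, 5341 were higher and 5630 lower (51.3%); 8128 genes were called in the same direction by both. Directions of genes with small differences therefore hold only for the scaling named: WRKY20 was lower by 0.54 ± 0.12 (SE) log2 units as deposited and at 0.05 after median-ratio scaling.

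The last comparison set the stages against each other at 38 °C. HSP101 was lower after véraison by 4.18 ± 0.17 (SE) log2 units in heated berries (limma adjusted p = 2.2e-08), and at -0.24 ± 0.17 at 16 °C, where it was not called (limma adjusted p = 0.24). With median-ratio scaling the difference at 16 °C was 0.29 and not called (limma adjusted p = 0.18), and with quantile normalization it was 0.49 and called higher after véraison (limma adjusted p = 0.024). GRIP22, GST4, GER7 and TL3 were the named genes with the largest rises, at 8.57 ± 0.16, 8.14 ± 0.21, 7.76 ± 0.26 and 6.11 ± 0.18 log2 units, and PPO, PSBP1 and VPRP1 had the largest falls, at -5.98 ± 0.38, -4.51 ± 0.18 and -4.28 ± 0.28. Their limma adjusted p-values lay between 4.9e-10 (GRIP22) and 3.9e-07 (VPRP1). All 10 aquaporins were lower (camera adjusted p = 4.9e-04, and adjusted p = 0.024 with an estimated correlation); with median-ratio scaling 8 were lower and 0 higher. In total 2889 genes were higher and 8900 lower, 75.5% of them lower, against 5396 and 5791 (51.8%) with median-ratio scaling, which moved the median by 0.43 log2 units.

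**Figure D4:**
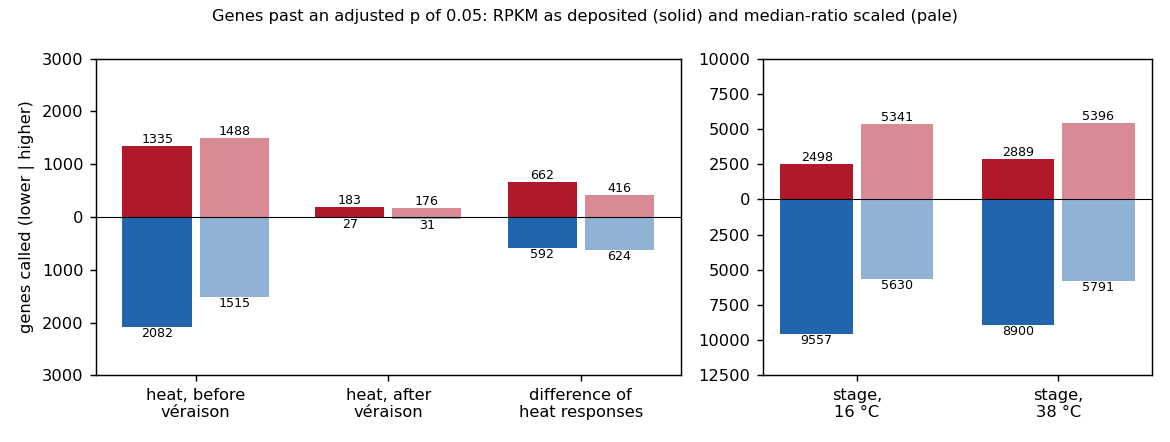
Number of genes past a limma adjusted p of 0.05 in each of the 5 comparisons, with higher genes above and lower genes below the zero line; solid bars use RPKM as deposited and pale bars RPKM after median-ratio scaling. The split of the stage comparison at 16 °C moved from 2498 higher and 9557 lower to 5341 and 5630, while the heat comparison after véraison stayed near 183 and 27 (176 and 31).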

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

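The 3 tests of the count of heat calls in this part were all chosen after that count had been seen. The heat response differed between stages for 1254 genes by the interaction in limma. The count was 934 and 1507 with pseudocounts of 0.1 and 5, 907 with no filter on low values, and 1266 with limma voom. Adding 1 to RPKM makes a change at low levels smaller, so some of these differences may come from the scale. Their share was not tested. Among named genes the difference (after minus before véraison, log2) was negative for HSP101 (-3.94), HsfA2 (-2.96), CHI4C (-2.07), DHAR (-2.06), WKRY (-1.64), BiP (-1.42), BG1 (-1.02), MRIP1 (-1.0), CIPK01 (-0.97), CYN (-0.93), CIPK20 (-0.65) and PIP2;2 (-0.65). It was positive for ADH3 (0.49), CIPK14 (0.76), VVYS1 (0.76), UVR1 (0.86), CCD4b (0.86), CBL01 (0.89), CIPK15 (0.90), CHS1 (0.98), GS1 (0.98), RD22-C (1.10), MYBCS1 (1.16), CIPK19 (1.16), MYB30 (1.22), PIP1;1 (1.29), FLS1 (1.35), bZIPC22 (1.39), MYBC2-L1 (1.75) and CHS2 (1.83). With median-ratio scaling ADH3, UVR1, CHS1 and FLS1 were not called (limma adjusted p = 0.11, 0.070, 0.077 and 0.059), with quantile normalization PIP2;2 and CHS1 were not (0.099 and 0.051), and with limma voom RD22-C, PIP1;1 and FLS1 were not (0.15, 0.13 and 0.14). Of the 1254 genes, 1196 were also called with heat before véraison. Both comparisons use the same pre-véraison libraries, so some overlap arises from that alone.

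Heat gave 3417 calls before véraison and 210 after it. Fewer reads left for other genes by abundant ripening transcripts are argued against as the whole cause (the median RPKM was 1.81 to 1.88 after and 3.26 to 3.70 before véraison, which a fall of many transcripts would also give): among 3278 genes with no fewer reads and no lower RPKM after véraison at 16 °C, 893 were called before and 90 after, a ratio of 0.101 ± 0.011 (counting SE), with 1267 and 486 at an unadjusted p under 0.05 (5550 and 1624 over all genes). The counting SE treats the calls as independent, though all come from the same libraries, so it leaves out the spread between libraries. The SD of replicate differences of log2(RPKM + 1) after véraison was 0.945 times that before, so the spread on this scale was not larger. This ratio does not decide the counts, since the fit shares the spread of each gene over all 4 groups. Both heat comparisons therefore use the same standard error for a gene. Genes chosen by their rise in 1 pair of pre-véraison libraries rose after véraison by 0.279 of their rise in the other pair (0.268 over 676 genes and 0.291 over 719), and genes chosen by their fall gave 0.147 (568 genes) and 0.160 (553 genes), which is consistent with a smaller response of the same genes. Centred on the median change of all genes, the ratios were 0.246 and 0.266 for the rises and 0.188 and 0.200 for the falls. The genes were chosen without regard to their level after véraison. Adding 1 to RPKM makes changes at low levels smaller, and this part of the ratios was not separated. A slower response after véraison, a difference in berry temperature and a difference between sampling days were not tested. Stage goes with weeks after flowering in this design.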

How the results depend on the processing

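All alternatives except limma voom, which was added after the data had been seen, were set before the data were examined. Over 23 alternatives, 4258 values of named genes were recomputed: 4114 kept direction and side of the threshold, 86 were no longer called, 29 became called in the same direction and 29 changed sign, of which 2 were called as deposited, 1 only in the alternative and 26 in neither; the cause was not tested. The 2 were WRKY20 between stages at 16 °C, at 0.045 with median-ratio scaling and 0.0093 with quantile normalization (-0.54 as deposited). The 1 was HSP101 between stages at 16 °C with quantile normalization, at 0.49 (limma adjusted p = 0.024; -0.24 as deposited); it was 0.29 with median-ratio scaling, not called. Called in neither with a scaling changed were HsfA2 between stages at 16 °C (0.16 with median-ratio scaling and 0.42 with quantile normalization; -0.24 as deposited), WRKY2 there (-0.093 scaled to equal totals), and WRKY20, SWEET15 and BiP with heat after véraison (-0.0013, 0.084 and -0.0079 with quantile normalization). The others came from leaving out 1 library, over which the ranges crossed 0 between stages at 16 °C for HsfA2 (-0.66 to 0.17; called, at -0.66, without replicate 2 of unheated post-véraison berries) and WRKY2 (-0.13 to 0.17), with heat before véraison for WRKY2 (-0.27 to 0.031), chit1a (-0.12 to 0.23) and METK4 (-0.027 to 0.10), and with heat after véraison for WRKY20 (-0.033 to 0.14), SWEET15 (-0.25 to 0.031), BiP (-0.014 to 0.079), CCD1 (-0.0022 to 0.17), MADS1 (-0.026 to 0.15), 4CL (-0.036 to 0.29), HT2 (-0.42 to 0.084), METK5 (-0.017 to 0.49), OPR3 (-0.24 to 0.086) and PSBP1 (-0.60 to 0.0096). Heat after véraison, 210 calls, gave 36 with only the 4 libraries compared and 126 with a replicate block within stage. Heat before véraison, 3417 calls, gave 2534 and 3049 in the same fits. Both fits leave fewer residual degrees of freedom, and the cause of the lower counts was not tested. A replicate block over all libraries gave 3157, 185, 1057, 11900 and 11630 calls for heat before and after véraison, the interaction and the stage difference at 16 and 38 °C. A fold change of at least 2 left 1089, 123, 805, 6227 and 5983, and an adjusted p under 0.01 left 1882, 122 and 555 in the first 3; stricter thresholds lower counts by construction. The 4 aquaporins called with heat before véraison became 2 with a pseudocount of 0.1, quantile normalization or an adjusted p under 0.01, and 1 with a fold change of at least 2. The correlation of the heat responses was 0.45 with limma voom; the cause was not tested. Leaving out each library in turn gave 2013 to 3362 calls for heat before véraison, 104 to 209 after it, 696 to 1061 for the interaction, 10751 to 12006 and 10288 to 11892 for the stage differences, 2 to 5 aquaporins and a correlation of 0.50 to 0.56; the lone library of a group was assumed to vary like the others. The low values came without replicate 2 of heated pre-véraison berries (2013; interaction 711), without replicate 1 (104; 696) or 2 (107; 748) of heated post-véraison berries, and for aquaporins without replicate 1 of unheated or heated pre-véraison berries (2 each). Stage differences were not fitted with a block within stage, nor the interaction with only 4 libraries. Of the alternatives for read counts, limma voom was the 1 run. Depth limits genes under 0.17 to 0.32 RPKM, the level of 3 reads on a gene of median length.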

Other observations

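The test of chance gene order was written before its result was seen; the 2 tests of mixed libraries and the comparison of gene lengths were chosen after related values had been seen, and the limits that define their gene sets were set then.

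Among 13893 tested genes placed in genome order, 1130 had risen with heat before véraison, and 181 pairs of these were neighbours. A permutation test of 10000 shuffles of the calls over the 13893 genes gave a mean of 91.7 and at most 135 pairs. Thus 0 percent of shuffles gave as many (permutation p = 1e-04, the smallest they can give), which argues against calls placed at random over these genes. The shuffles did not keep expression level and treated tandem copies as separate genes. Genes that fell gave 309 neighbouring pairs against a mean of 223 and at most 267. The longest runs of risers held 16 genes (LOC100242632 to LOC100254504), 12 genes (LOC100261190 to LOC100268056) and 8 genes (LOC100261497 to LOC100242821), with mean log2 rises of 3.90, 6.41 and 7.34. Tandem gene copies may share regulation or share reads; with no sequence used here, neither was tested.

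In unheated post-véraison berries, 38 genes strongly induced by heat before véraison summed to 179 RPKM in replicate 1 and 233 in replicate 2, and 31 of them were higher in replicate 2. The excess was 0.27 percent of their level in heated pre-véraison berries. A set of 24 genes not changed by heat and near absent after véraison summed to 16.3 and 25.4 RPKM, an excess of 0.26 percent and 0.932 times the share of the heat-induced genes. The same 24 genes summed to 21.3 and 13.0 RPKM in the 2 heated post-véraison libraries, so replicates of this stage differed there too. A single share for every heat-induced gene gave a chi-square per degree of freedom of 3.22 against counting error, which leaves out the spread between berries. A few reads from a heated pre-véraison library and a difference between the berries sampled therefore cannot be told apart. Without replicate 2, heat after véraison gave 148 calls, and without replicate 1 it gave 184.

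Of the genes that rose with heat before véraison, 4 rose more after it by the interaction, and they were singled out after their values were seen: LOC100245897 (0.99 before, 3.14 after, log2), LOC100251039 (1.15 and 3.21), LOC100256196 (1.12 and 3.27) and LOC100261290 (0.93 and 2.56). Their levels were alike (50.1 to 63.0 RPKM in heated post-véraison berries).

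Genes that rose with heat before véraison had a median recovered length of 1383 bp (1329 genes), against 1502 bp for sets matched on expression (lowest of 10000 sets, 1402). Risers over 8-fold had 954 bp (136 genes, matched 1510.5), and fallers 1623.5 bp (2078 genes, matched 1511.5).

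Some abundant transcripts differed between replicates. LOC100244292 was at 7406 and 26178 RPKM in the 2 unheated pre-véraison libraries (3.53-fold) and LOC100248902 at 7033 and 23187 RPKM (3.30-fold), and differed less between the unheated post-véraison libraries (20736 and 9873 RPKM for LOC100244292, 18455 and 10115 RPKM for LOC100248902). LOC100245999, the most abundant gene by the mean of the unheated post-véraison libraries, was at 37174 and 39940 RPKM after véraison and at 2270 and 2855 RPKM before it.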
